A study of Mus musculus with 9 samples.

How the data were processed

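The samples were CD45-positive cells sorted from subcutaneous YUMM 2.1 melanomas in C57BL/6J mice, 3 libraries each from mice given control IgG, anti-B7-H3 or anti-PD1. Per the labels' protocols, treatment began at tumour volumes of 20 to 50 mm3, and at least 500 ng of RNA with an integrity number of at least 7.0 was taken into SMART-Seq v4 cDNA synthesis, depletion of ribosomal RNA and Nextera XT library preparation. These kits do not mark the strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Genome build GRCm38 and FastQC 0.11.8 are named per the submitters' processing notes. The quantifier, its version and its settings are not given in the sources used here.

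Each deposited file lists, per the file headers, a length, an effective length, a TPM value and an estimated count for 58083 transcripts of 1 library. The deposited estimated counts are not normalised and not whole. The deposited TPM values have the same sum in each library. Of the lengths, 87.3% are multiples of 3, as coding sequences without untranslated regions would give, so lengths here are coding lengths.

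Transcripts were assigned to genes with GENCODE M21, which matched 57409 of them, 57105 with the same version, and left 674 unmatched and unused. Estimated counts were summed over the transcripts of each of 22136 genes and rounded to whole numbers. Coordinates are those of GENCODE M21 on GRCm38. Library totals ran from 14487012 to 31533106 counts, so a floor of 3 counts in a library lies between 0.0954 and 0.208 CPM. Reads were amplified by PCR without molecular identifiers, so 95% counting intervals (exact, from the counts of both groups) and floors cover counting error only.

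All 9 libraries entered 1 edgeR 4.0.16 fit in R 4.3.3, with TMM factors, genes kept by filterByExpr with the group labels (13178 of them), a mean per group and no covariate, robust quasi-likelihood dispersions and glmQLFTest for each of 3 comparisons. P-values were adjusted by the method of Benjamini and Hochberg over the tested genes, at a threshold of 0.05. CPM values of single genes use TMM-scaled library sizes, and those of gene classes and of repeat-like gene models use unscaled ones. For genes with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over that group. For genes with 1 to 3 counts it is the ratio of CPM with its interval. Such ratios use counts pooled over the libraries of each group, so they differ from ratios of the mean CPM.

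Gene lists for immune and other cell types, for pathways and for RNA quality, 56 in all, were written down before the data were examined, as were the tests, the rule for named genes and the other settings listed further on. The 54 lists with at least 5 tested members were tested by camera in limma 3.58.1, at its preset correlation of 0.01 and on log2 CPM with a prior count of 2, and 162 p-values were adjusted together. Each list was also tested with a correlation estimated from the data and by fry, whose p asks whether a list moves in 1 direction on balance without comparing it with other genes. The exact two-sided permutation test of a list's mean between 3 and 3 libraries cannot give a p below 0.1. Marker lists describe shares of RNA, not numbers of cells. Some genes belong to several lists, so the lists are not independent of each other.

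Named genes follow a rule. In each comparison it takes, among genes past the test with a mean of at least 5 CPM in the higher group and no overlap of the groups, and leaving out clone names, the 12 largest rises and the 12 largest falls. Where fewer than 5 genes pass, it takes the 10 with the smallest p under the same conditions. It adds the genes of the antibody targets and, for each list described, up to 4 tested members with the smallest p. Any gene outside it is said to have been chosen after its values were seen.

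The fit was tested on simulated counts modelled on anti-B7-H3 against IgG, with 200 changed genes among 12771. It recovered 6% of 50 genes changed 2-fold, 54% of 50 changed 4-fold, 78% of 50 changed 8-fold and 70% of 50 changed 16-fold, with 4 false calls. Of 50 random lists, camera gave 1 a p under 0.05. The simulated genes were independent of each other, so this check does not cover lists whose members vary together.

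Besides the other list tests, 21 other settings were fixed: DESeq2 1.42.0, its size factors in edgeR, upper-quartile factors, limma-voom with quality weights, no filter and a stricter filter of 5 CPM in 3 libraries, length-scaled TPM counts, the table without the 20 most abundant genes or without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, only the 6 libraries of the groups compared, non-robust dispersions, the replicate number as a block and each library left out in turn. A further 3 settings, chosen after seeing the data, left out libraries that stood apart or genes at 0 in any library. The effects against the shared controls were set beside 100 simulated sets of unchanged groups fitted the same way. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.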

Results

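RNA was sequenced in bulk from CD45-positive immune cells sorted out of subcutaneous YUMM 2.1 tumours, a mouse melanoma line grown in C57BL/6J mice. There were 9 libraries in 3 groups of 3, from mice given a control IgG, an antibody against B7-H3 (a surface protein of the B7 family, gene Cd276) or an antibody against PD1 (an inhibitory receptor of T cells, gene Pdcd1). A combination of antibodies described in the series' design was not analysed here. Nothing in the labels says that the replicates of a group are separate animals, so the p-values of single genes rest on the spread between these samples alone. Those from camera compare a list with the other genes. They also depend on the number of genes and on the correlation assumed between them. The IgG control libraries 1, 2 and 3 held 18474479, 14487012 and 20477257 estimated counts. The anti-B7-H3 libraries held 15091916, 29353809 and 31533106, and the anti-PD1 libraries held 30119530, 28124402 and 24257522. A floor of 3 counts in a library corresponded to 0.0954 to 0.208 CPM (counts scaled to a common library total). Genes with at least 10 counts numbered from 10791 in IgG control 2 to 13201 in anti-B7-H3 1.

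A pair of libraries stood apart from the rest. IgG control 2 lay at 192 on the first principal component, which held 35.9% of the variance, against -54.9 to 31.1 for the other 8. It had 1896 of the 13178 tested genes at 0, and anti-PD1 3, which lay apart on the next component, had 1248. IgG control 3 had 822 and each of the other 6 had between 224 and 308. Anti-B7-H3 1 carried 0.547% of its counts on transcripts that matched no gene, against at most 0.316% elsewhere. The values of groups below are mean CPM ± SD of 3 libraries, fold changes are log2 ± SE from edgeR, and adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for gene lists.

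The genes of the antibodies' targets and of related checkpoints were examined first, although no antibody removes a gene. Sirpa (chromosome 2, 129592835 to 129632228, GRCm38), the phagocyte receptor that binds CD47, rose from 5.90 ± 2.34 CPM in the controls to 49.2 ± 6.11 with anti-B7-H3 and to 42.3 ± 22.5 with anti-PD1 (edgeR adjusted p = 0.00803 and 0.00749). Pdcd1lg2, which encodes the PD1 ligand PD-L2 (chromosome 19, 29410919 to 29471161), rose with anti-PD1 by 1.79 ± 0.38, and its change of 1.39 with anti-B7-H3 missed the threshold (edgeR adjusted p = 0.0441 and 0.214). For Cd274, encoding PD-L1 (chromosome 19, 29367455 to 29388095), the changes were 0.80 and 1.71, short of the threshold (edgeR adjusted p = 0.599 and 0.0592). Pdcd1 (chromosome 1, 94038305 to 94052553) differed by -0.81 and -0.32, Cd47 (chromosome 16, 49800533 to 49915010) by -0.12 and -0.01, and Ptprc, encoding CD45 (chromosome 1, 138062861 to 138175708), by -0.23 and -0.18. None of these 3 passed the test, with edgeR adjusted p-values from 0.607 to 0.996. Cd276 (chromosome 9, 58524298 to 58555437) averaged 0.284 CPM in the controls, 2.21 with anti-B7-H3 and 0.578 with anti-PD1, with at most 85 counts in a library. All 3 anti-B7-H3 libraries, at 1.19, 2.83 and 2.62 CPM, lay above the controls, at 0.852, 0 and 0, but its changes of 2.93 ± 2.02 and 1.00 ± 1.91 did not pass the test (edgeR adjusted p = 0.776 and 0.907).

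The comparison of anti-B7-H3 with IgG asked how blocking B7-H3 changes the immune cells of the tumour. RNA of macrophages and other myeloid cells was higher with anti-B7-H3. The mean of the macrophage marker list was 11.1-fold higher, that of the complement list 8.54-fold, that of the neutrophil list 4.96-fold and that of the chemokine list 4.14-fold. Without IgG control 2 the macrophage value was 7.20-fold. Lyz2, the lysozyme of macrophages and neutrophils, rose from 122 ± 59.8 to 1050 ± 283 CPM (n = 3 per group, edgeR adjusted p = 0.0051). Of 13178 genes, 112 passed the test at an adjusted p of 0.05, 109 higher and 3 lower. All 109 were higher in each anti-B7-H3 library than in any control library, which selection by the test favours. Among all tested genes, 1313 were arranged in this way and 724 the other way. Both directions together made up 15.5%, where chance gives 10%.

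**Figure D1:**
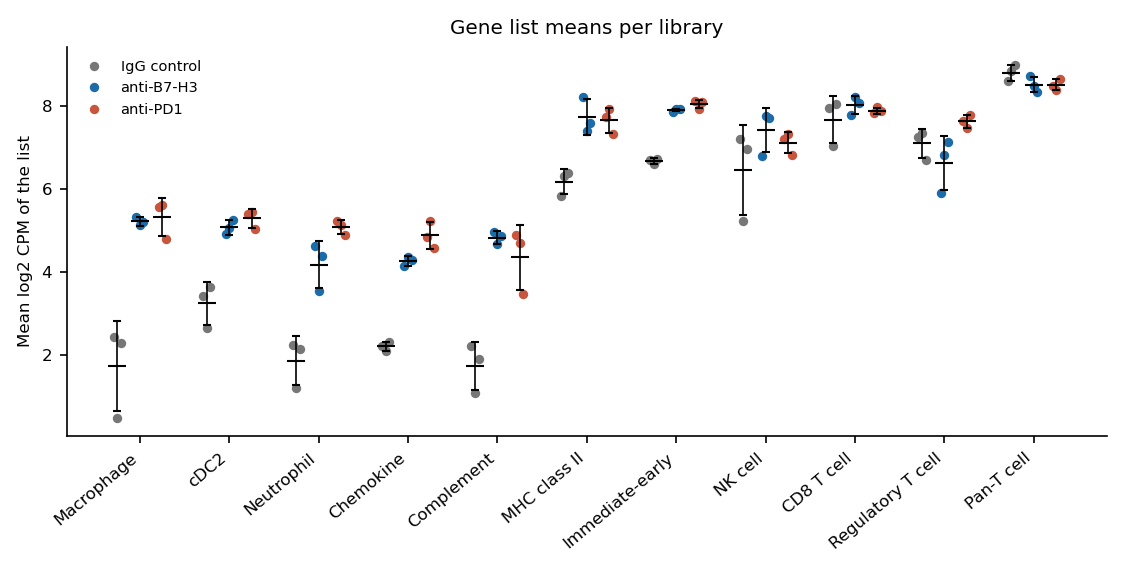
Mean log2 CPM of the tested members of 11 gene lists in each library (points, coloured by group), with the mean and SD of the 3 libraries of a group (bars). The macrophage, conventional dendritic cell 2 (cDC2), neutrophil, chemokine and complement lists lie higher in all libraries of both antibody groups than in the controls, and the pan-T list differs little by comparison.

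Of 18 tested macrophage markers, 8 rose over all genes and 15 adjusted over the list alone (camera adjusted p = 1.38e-15, and adjusted p = 0.042 with an estimated correlation). Cd68, a lysosomal glycoprotein of macrophages, rose by 2.16 ± 0.29, Apoe, the lipid carrier, by 2.85 ± 0.39, and C1qb by 3.71 ± 0.49. Among the markers of cDC2, 4 of 13 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 1.11e-08, and adjusted p = 0.0276 with an estimated correlation). Their lectin Mgl2 went from 17.5 ± 5.04 to 190 ± 68.6 CPM, and the transcription factor Klf4 rose by 2.57 ± 0.33. Mgl2 is also a member of a list of macrophage states below. Klf4, and Nr4a1 of the monocyte list, are also members of the immediate-early list below. Of 15 neutrophil markers, 4 rose over all genes and 11 adjusted over the list alone (camera adjusted p = 7.73e-10, and adjusted p = 0.0346 with an estimated correlation). Csf3r, the receptor of G-CSF, rose by 3.41 ± 0.52 and the calprotectin subunit S100a9 by 1.93 ± 0.26. The monocyte list had 2 of 14 members higher over all genes and 5 adjusted over the list alone, Hp (haptoglobin) by 2.14 ± 0.28 and Nr4a1 by 1.63 ± 0.26. Its call did not hold with an estimated correlation (camera adjusted p = 1.02e-05, and adjusted p = 0.172 with an estimated correlation).

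Genes tied to opposite macrophage states rose side by side. Of 16 genes of the alternatively activated (M2) type, 5 rose over all genes and 11 adjusted over the list alone, and of 15 of the classically activated (M1) type, 2 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 1.49e-12 and 7.08e-07, and adjusted p = 0.028 and 0.0303 with an estimated correlation). In the M2 list, Arg1, the arginine-degrading arginase, went from 106 ± 80.4 to 1019 ± 169 CPM and the mannose receptor Mrc1 from 1.76 ± 1.96 to 37.0 ± 6.48. In the M1 list, the cytokine gene Il1b went from 30.2 ± 21.1 to 386 ± 110 CPM and Irf5 rose by 1.25 ± 0.19. Of 17 genes of lipid-associated macrophages, 5 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 1.52e-10, and adjusted p = 0.042 with an estimated correlation), with Spp1 (osteopontin) up by 2.85 ± 0.40 and the elastase gene Mmp12 by 2.71 ± 0.39.

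Chemokine genes were higher, 7 of 23 over all genes and 14 adjusted over the list alone (camera adjusted p = 4.92e-15, and adjusted p = 0.0245 with an estimated correlation). The neutrophil attractant Cxcl2 rose by 3.03 ± 0.29, Ccl6 by 2.83 ± 0.31 and Ccl9 by 2.50 ± 0.32. Of 17 complement genes, 5 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 1.14e-12, and adjusted p = 0.042 with an estimated correlation), among them C5ar1, the C5a receptor, by 3.21 ± 0.37 and C1qa by 3.25 ± 0.50. The lysosome list was higher, 3 of 26 genes over all genes and 9 adjusted over the list alone (camera adjusted p = 1.8e-06, and adjusted p = 0.0362 with an estimated correlation), with the cathepsin Ctsh up by 1.87 ± 0.26 and Grn by 0.98 ± 0.19. Of 22 immediate-early genes, which also respond to tissue dissociation, 7 rose over all genes and 19 adjusted over the list alone (camera adjusted p = 4.48e-18, and adjusted p = 0.0131 with an estimated correlation). Atf3 rose by 3.13 ± 0.26, and Fos went from 575 ± 113 to 1571 ± 63.4 CPM.

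Antigen presentation by MHC class II, phagocytosis with its Fc receptors, inflammation and the TGF-beta and IL-10 list were called higher by camera and by fry (fry adjusted p = 0.00262 to 0.0305), but not with an estimated correlation. Of 12 class II genes, 7 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 1.54e-11, and adjusted p = 0.148 with an estimated correlation). H2-Ab1 rose by 2.38 ± 0.29 and H2-DMb1 by 2.11 ± 0.21, although near-identical H2 genes can share reads. Of 25 phagocytosis genes, 4 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 2.96e-08, and adjusted p = 0.135 with an estimated correlation), including the inhibitory Fc receptor Fcgr2b by 3.13 ± 0.27 and the paired receptor Pilra by 2.41 ± 0.37. Of 27 genes of TNF and NF-kB inflammation, 6 rose over all genes and 13 adjusted over the list alone (camera adjusted p = 2.95e-10, and adjusted p = 0.0792 with an estimated correlation), with the interleukin 1 receptor antagonist Il1rn up by 2.66 ± 0.31 and Ier3 by 2.33 ± 0.26. From the TGF-beta and IL-10 list, 3 of 19 rose over all genes and 4 adjusted over the list alone, Tgfbi by 3.26 ± 0.43 and the vascular growth factor Vegfa by 1.92 ± 0.22 (camera adjusted p = 0.00481, and adjusted p = 0.345 with an estimated correlation). That list's call was also lost without IgG control 3 (camera adjusted p = 0.0951). The unfolded protein response list was likewise higher (camera adjusted p = 0.00055, fry adjusted p = 0.0116, and adjusted p = 0.223 with an estimated correlation). Hypoxia and migratory dendritic cell lists were called higher by camera alone, at medians of 0.49 and 0.84 (camera adjusted p = 0.00318 and 0.00818, fry adjusted p = 0.0812 and 0.0904). The migratory dendritic cell call was lost without anti-B7-H3 3 (camera adjusted p = 0.128).

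The pan-T, helper and regulatory T cell lists were called lower by camera, and those of NK, B and plasma cells higher. Few single genes passed the test. None of these calls held by fry (fry adjusted p = 0.121 to 0.339) or with an estimated correlation. The exact permutation p of the lists' means ran from 0.1 to 0.4. The pan-T list lay lower, at a median of -0.28 (-0.43 without IgG control 1), with none of its 18 genes past the test over all genes or adjusted over the list alone (camera adjusted p = 0.00033, and adjusted p = 0.37 with an estimated correlation). The helper T cell list had a median of -0.56 and 1 lower gene, the interleukin 7 receptor Il7r, which fell by 1.45 ± 0.27, over all genes and adjusted over the list alone (camera adjusted p = 0.00092, and adjusted p = 0.29 with an estimated correlation). The regulatory T cell list lay at -0.65 with no gene past either adjustment (camera adjusted p = 0.000569, and adjusted p = 0.393 with an estimated correlation). That median was -0.30 without IgG control 2, and the list's mean difference of -0.48 became -0.12 without anti-B7-H3 1 and -0.74 without anti-B7-H3 3. Markers of NK cells were higher at a median of 0.86 and those of B cells at 1.85, all 18 of the latter positive, again with no gene past either adjustment (camera adjusted p = 0.00041 and 0.000321, and adjusted p = 0.536 and 0.37 with an estimated correlation). The NK cell median was 0.46 without IgG control 2, and the B cell median 0.79 without anti-B7-H3 1. Plasma cell markers, at a median of 1.01, had all 13 genes positive, 0 past the test over all genes and 2 higher adjusted over the list alone (camera adjusted p = 0.000352, and adjusted p = 0.353 with an estimated correlation). Their median was 1.64 without IgG control 2 and 0.59 without IgG control 3. The list of gamma-delta T cells and innate lymphoid cells was higher at 0.71 (camera adjusted p = 0.0239, and adjusted p = 0.345 with an estimated correlation). That call was lost without IgG control 1, IgG control 2 or anti-B7-H3 3 (camera adjusted p = 0.0691, 0.0811 and 0.0844). CD8 T cells, at a median of 0.15, were not called (camera adjusted p = 0.371). Type I interferon genes lay at a median of -0.22, with 2 of 30 lower over all genes, and 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00382, and adjusted p = 0.205 with an estimated correlation). Their mean differed by only -0.01. The antiviral genes Ifit3 and Ifit1 fell by 1.44 ± 0.25 and 1.40 ± 0.27, where reads of Ifit3 and its near copy Ifit3b may be split between them.

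The largest rises included genes close to absent from the controls. Mmp13, a collagenase, had 3 counts over the 3 controls, and its CPM ratio was 163 with a 95% counting interval of 55.4 to 791. The light chain segment Igkv12-89 had 2 control counts and a ratio of 2396 (663 to 19788), and like Iglv3, which rose by 4.81 ± 0.85, it may share reads with related segments. F7 (coagulation factor VII) rose by 5.50 ± 0.80, the myeloid receptor Clec5a by 4.92 ± 0.95 and the Fc receptor-like Fcrlb by 4.20 ± 0.78. Tnfaip2 went from 3.08 ± 3.07 to 35.2 ± 10.6 CPM and the eosinophil-attracting chemokine Ccl24 from 29.6 ± 28.6 to 471 ± 263 CPM. Markers of cells that a CD45 sort should remove were also higher by the preset test, at medians of 2.55 for melanoma and 3.28 for fibroblasts, with no gene past the test over all genes, and 0 and 1 adjusted over the list alone (camera adjusted p = 0.00793 and 0.00576, and adjusted p = 0.393 and 0.236 with an estimated correlation). The fibroblast call was also lost without IgG control 1 (camera adjusted p = 0.0691). Erythroid markers, which the sort should also remove, were lower at a median of -4.04, or -1.78 without IgG control 3, with 0 of 7 genes past either adjustment (camera adjusted p = 0.0164, and adjusted p = 0.444 with an estimated correlation). Their call was lost without IgG control 1 or 3 (camera adjusted p = 0.0652 and 0.196). The 112 calls numbered 64, 60 and 59 without anti-B7-H3 1, 2 or 3, with none of the 3 lower genes among them, 73 without anti-PD1 2, which is in neither group compared, and 44 when the anti-PD1 libraries took no part. Of the 45 named genes called, 29 kept their call without each library in turn, and 16 lost it without at least 1: Arg1, Ccl24, Clec5a, Csf3r, Fcrlb, Grn, Ifit1, Ifit3, Igkv12-89, Iglv3, Il1b, Il7r, Irf5, Mrc1, Nr4a1 and Tnfaip2. The library left out ended 10, 9 and 8 of these calls for IgG control 1, 2 and 3, 11, 14 and 14 for anti-B7-H3 1, 2 and 3, and 9, 10 and 6 for anti-PD1 1, 2 and 3.

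**Figure D2:**
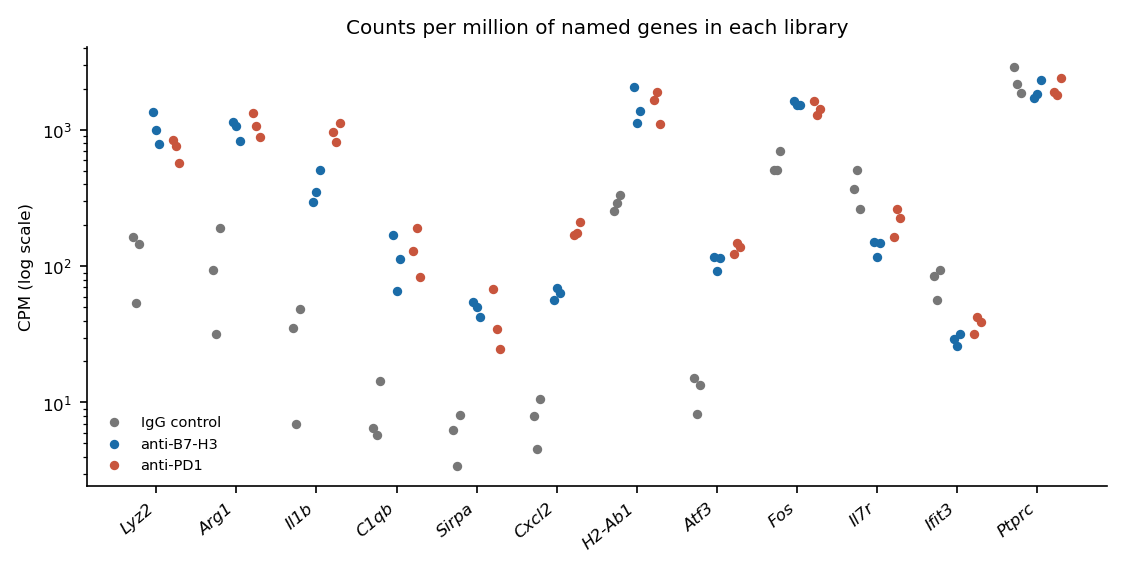
CPM of 12 named genes in each library on a log scale, with points coloured by group. Lyz2, Arg1, Il1b, C1qb, Sirpa, Cxcl2, H2-Ab1, Atf3 and Fos lie higher in all 6 antibody libraries than in the 3 controls, Il7r and Ifit3 lie lower with anti-B7-H3, and Ptprc shows no change past the test. Il7r and Ifit3 also average lower with anti-PD1, short of the test.

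The comparison of anti-PD1 with IgG asked the same of PD1 blockade. Myeloid RNA was again higher, and the rises of inflammatory and neutrophil genes were steep. The mean of the macrophage list was higher by 3.59 (log2), that of the neutrophil list 9.29-fold, that of the chemokine list 6.36-fold and that of the TNF and NF-kB list 4.91-fold. Without IgG control 2 the macrophage value was 2.96. Il1b went from 30.2 ± 21.1 to 980 ± 157 CPM (n = 3 per group, edgeR adjusted p = 0.00531) and Cxcl2 from 7.71 ± 3.01 to 186 ± 22.9 (edgeR adjusted p = 0.000234). The heavy chain gene Ighm rose as well, from 4240 ± 1613 to 18009 ± 4379 CPM (edgeR adjusted p = 0.00813). Of 13178 genes, 229 passed, 227 higher and 2 lower. All 227 were higher in each anti-PD1 library than in any control library, which selection by the test again favours. Among all tested genes, 1316 were arranged in this way and 859 the other way. Both directions together made up 16.5%, where chance gives 10%.

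Of 18 macrophage markers, 9 rose over all genes and 13 adjusted over the list alone (camera adjusted p = 6.3e-16, and adjusted p = 0.042 with an estimated correlation), among them Cd68 by 2.42 ± 0.29. Of 15 neutrophil markers, 7 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 1.45e-14, and adjusted p = 0.0245 with an estimated correlation). S100a9 went from 30.6 ± 6.94 to 297 ± 59.6 CPM, S100a8 rose by 2.91 ± 0.35, G0s2 by 3.98 ± 0.39 and Csf3r by 4.27 ± 0.54. Of 13 cDC2 markers, 6 rose over all genes and 9 adjusted over the list alone, with Mgl2 going from 17.5 ± 5.04 to 244 ± 42.9 CPM and Klf4 up by 2.87 ± 0.33 (camera adjusted p = 3.49e-10, and adjusted p = 0.0245 with an estimated correlation). The list of migratory dendritic cells had 1 of 14 members higher over all genes and 7 adjusted over the list alone, and its chemokine Ccl17 rose by 2.05 ± 0.35 (camera adjusted p = 3.92e-07, and adjusted p = 0.0781 with an estimated correlation). Of 14 monocyte markers, 3 rose over all genes and 5 adjusted over the list alone, including Hp by 2.72 ± 0.29 and Nr4a1 by 1.97 ± 0.26 (camera adjusted p = 0.000788, and adjusted p = 0.271 with an estimated correlation). Klf4 and Nr4a1 are members of the immediate-early list too. Among 7 eosinophil markers, Ear2 rose by 2.60 ± 0.52, the single gene past the test over all genes and adjusted over the list alone, although Ear2 has near copies that can share its reads (camera adjusted p = 0.00197, and adjusted p = 0.0781 with an estimated correlation).

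M2-type genes were higher, 7 of 16 over all genes and 15 adjusted over the list alone, and so were M1-type genes, 3 of 15 over all genes and 8 adjusted over the list alone (camera adjusted p = 3.1e-14 and 1.85e-07, and adjusted p = 0.0276 and 0.028 with an estimated correlation). Arg1 went from 106 ± 80.4 to 1097 ± 225 CPM and Mrc1 rose by 4.28 ± 0.79. The costimulatory ligand Cd80, of the M1 list, rose by 2.02 ± 0.43. Of 17 genes of lipid-associated macrophages, 7 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 9.18e-13, and adjusted p = 0.0346 with an estimated correlation). Spp1 rose by 3.73 ± 0.41 and Plin2, which coats lipid droplets, by 1.53 ± 0.20. Of 26 lysosome genes, 4 rose over all genes and 7 adjusted over the list alone, Ctsl by 2.54 ± 0.38 and Lgmn by 1.73 ± 0.33 (camera adjusted p = 2.98e-05, and adjusted p = 0.0476 with an estimated correlation).

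Of 23 chemokine genes, 10 rose over all genes and 17 adjusted over the list alone, Ccl6 by 3.29 ± 0.32 and Ccl9 by 2.72 ± 0.32 (camera adjusted p = 7.07e-19, and adjusted p = 0.0242 with an estimated correlation). Of 27 genes of TNF and NF-kB inflammation, 14 rose over all genes and 18 adjusted over the list alone, Il1rn by 3.69 ± 0.33 and Ccl3 by 2.11 ± 0.28 (camera adjusted p = 4.48e-18, and adjusted p = 0.0362 with an estimated correlation). Of 22 immediate-early genes, 12 rose over all genes and 20 adjusted over the list alone (camera adjusted p = 7.07e-19, and adjusted p = 0.0131 with an estimated correlation). Atf3 rose by 3.46 ± 0.27, and Zfp36, which destabilises cytokine transcripts, went from 494 ± 91.2 to 1584 ± 189 CPM.

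Further lists were called higher by camera and by fry (fry adjusted p = 0.00165 to 0.0158), but not with an estimated correlation. Complement had 5 of 17 genes higher over all genes and 9 adjusted over the list alone, with C5ar1 up by 4.20 ± 0.38 (camera adjusted p = 9e-10, and adjusted p = 0.0689 with an estimated correlation). MHC class II had 8 of 12 higher over all genes and 10 adjusted over the list alone, with H2-Ab1 up by 2.41 ± 0.29 (camera adjusted p = 7.82e-10, and adjusted p = 0.172 with an estimated correlation). Phagocytosis had 5 of 25 higher over all genes and 11 adjusted over the list alone, with Fcgr2b up by 3.13 ± 0.27 (camera adjusted p = 1.09e-09, and adjusted p = 0.105 with an estimated correlation). Hypoxia genes had 6 of 21 higher over all genes and 9 adjusted over the list alone, Vegfa by 2.52 ± 0.23 and the oxygen sensor Egln3 by 1.62 ± 0.27 (camera adjusted p = 1.41e-08, and adjusted p = 0.141 with an estimated correlation). Of the genes of the unfolded protein response, 4 of 20 rose over all genes and 7 adjusted over the list alone, Creld2 by 1.33 ± 0.21 and Sdf2l1 by 0.86 ± 0.18 (camera adjusted p = 3.59e-08, and adjusted p = 0.0829 with an estimated correlation). Heat-shock genes had 3 of 16 higher over all genes and 9 adjusted over the list alone, Hspb1 by 2.35 ± 0.44 and Bag3 by 1.88 ± 0.38 (camera adjusted p = 5.42e-06, and adjusted p = 0.205 with an estimated correlation). The TGF-beta and IL-10 list had 5 of 19 higher over all genes and 7 adjusted over the list alone, among them Arg1 and Vegfa (camera adjusted p = 2.64e-05, and adjusted p = 0.172 with an estimated correlation). Inflammasome and interleukin 1 genes had 2 of 16 higher over all genes and 3 adjusted over the list alone, among them Il1b and Il1rn (camera adjusted p = 0.0466, and adjusted p = 0.268 with an estimated correlation). That last call held without IgG control 2 or anti-PD1 2 and was lost without any 1 of the other 7 libraries (camera adjusted p of 0.0506 or more).

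Plasma cell markers were higher by camera with both antibodies, the mean of the list being 3.30-fold with anti-PD1 and 2.96-fold with anti-B7-H3, but not with an estimated correlation (camera adjusted p = 8.76e-07 and 0.000352, and adjusted p = 0.217 and 0.353 with an estimated correlation). The value for anti-PD1 was 2.16-fold without anti-PD1 1 and 5.19-fold without anti-PD1 3. In mean log2 CPM, anti-PD1 3 lay at 4.05, inside the control range of 2.86 to 4.27, and the other 5 antibody libraries lay above it. Of the 13 markers with anti-PD1, 4 rose over all genes and 9 adjusted over the list alone. Igkc, the kappa light chain constant region, went from 2093 ± 1278 to 9481 ± 2389 CPM, the joining chain Jchain rose by 1.88 ± 0.40 and the transcription factor Irf4 by 2.02 ± 0.40. Of 18 B cell markers, 2 rose over all genes and 2 adjusted over the list alone, Ighm by 2.09 ± 0.32 and Iglc2 by 2.48 ± 0.48 (camera adjusted p = 0.0312, and adjusted p = 0.634 with an estimated correlation). Both belong to immunoglobulin loci, where similar segments can share reads. The B cell call was also lost without IgG control 1, anti-PD1 1 or anti-PD1 2 (camera adjusted p = 0.296, 0.0565 and 0.265). Immunoglobulin genes took 4.98%, 3.89% and 3.05% of the counts in the anti-PD1 libraries, against 1.17%, 1.43% and 0.420% in the controls.

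Among the T cell lists, 1 was called lower and 1 higher by camera, and neither by fry (fry adjusted p = 0.176 and 0.113). The pan-T list had a median of -0.34 (-0.20 without IgG control 3) with no gene past either adjustment (camera adjusted p = 0.00132, and adjusted p = 0.417 with an estimated correlation). Helper T cells had a median of 0.09 and a mean difference of 0.08, opposite in sign to the test's direction, and were not called (camera adjusted p = 0.934). Neither regulatory T cells, at a median of 0.14, nor CD8 T cells, at 0.10, were called (camera adjusted p = 0.244 and 0.561). Gamma-delta T cells and innate lymphoid cells were higher at a median of 1.16 (camera adjusted p = 0.0171, and adjusted p = 0.331 with an estimated correlation), a call lost without anti-PD1 2 (camera adjusted p = 0.0705). NK cell markers were called higher by camera as well, at a median of 0.51 (camera adjusted p = 0.0123, and adjusted p = 0.697 with an estimated correlation). That NK cell call was lost without IgG control 2 or anti-PD1 2 (camera adjusted p = 0.567 and 0.0612). Genes of the cytosolic ribosomal proteins had a median of -0.53, with 0 of 68 past the test over all genes or adjusted over the list alone (camera adjusted p = 0.000331, and adjusted p = 0.804 with an estimated correlation), and without IgG control 3 the median was 0.05 and the camera adjusted p 0.965. Without IgG control 2 the median was -0.80. Type I interferon genes had a median of -0.07 against a mean difference of 0.12 and were not called (camera adjusted p = 0.321). Adjusted over the list alone, 3 of 30 were lower and 1 higher, and over all genes 1 was higher. Ifit3 averaged 37.7 CPM with anti-PD1 and 79.0 in the controls, Ifit1 31.0 and 62.0, and Il7r 218 and 380, none past the test. Of the lists of other cells, fibroblast markers lay at a median of 4.24, or 3.72 with genes absent from a group set at their bound, with 0 of 10 past the test over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000899, and adjusted p = 0.172 with an estimated correlation). Melanoma markers, at 2.22, were not called (camera adjusted p = 0.0842). Erythroid markers were lower at -3.57, or -1.81 without IgG control 3, with 0 of 7 genes past either adjustment (camera adjusted p = 0.0132, and adjusted p = 0.43 with an estimated correlation). Their call was lost without IgG control 3 or anti-PD1 3 (camera adjusted p = 0.142 and 0.0846).

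Some of the largest rises again started from a near absence in the controls. Nkd2, an inhibitor of Wnt signalling, had no control counts and was at least 97.3-fold higher against a floor of 3 counts over the group, at 5.36 ± 1.70 CPM. Col4a2, a collagen of basement membranes, had 1 control count and a ratio of 400 with a 95% counting interval of 71.4 to 15812, Mmp13 had 3 and a ratio of 194 (66.1 to 942), and the segment Igkv12-89 had 2 and a ratio of 2215 (613 to 18293). Acod1, which makes itaconate in activated macrophages, went from 2.05 ± 1.81 to 98.2 ± 9.93 CPM. Mmp19 rose by 6.91 ± 1.29, the stress cytokine Gdf15 by 6.73 ± 1.32, Cd300ld by 6.09 ± 1.20, the collagen chaperone Serpinh1 by 5.50 ± 1.14, Clec5a by 5.49 ± 0.98, Fcgr4 by 5.38 ± 1.12 and Iglv3 by 5.34 ± 0.87. Of the 2 lower genes, Rpa1, which binds single-stranded DNA, fell by 0.85 ± 0.18, and Zfp109, chosen after its values were seen, went from a mean of 4.55 to 0.0123 CPM. Its ratio from pooled counts was 346, with a 95% counting interval of 61.5 to 13710. The 229 calls numbered 113 without anti-PD1 1 and 116 without anti-PD1 2, with no lower gene in either case, and 136 when the anti-B7-H3 libraries took no part. Of the 61 named genes called, 32 kept their call without each library in turn, and 29 lost it without at least 1: Acod1, Arg1, Bag3, Ccl17, Cd300ld, Cd80, Clec5a, Col4a2, Ear2, Egln3, Fcgr4, Gdf15, Hdc, Hspb1, Igkc, Iglc2, Iglv3, Irf4, Jchain, Lgmn, Mmp19, Mrc1, Nkd2, Pdcd1lg2, Rpa1, Sdf2l1, Serpinh1, Slc2a1 and Zfp109. The library left out ended 19, 7 and 15 of these calls for IgG control 1, 2 and 3, 10, 17 and 16 for anti-B7-H3 1, 2 and 3, and 25, 25 and 16 for anti-PD1 1, 2 and 3.

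The direct comparison of anti-B7-H3 with anti-PD1 asked whether the antibodies differ in their effect. Neutrophil RNA was lower with anti-B7-H3 than with anti-PD1, the mean of the list being 0.534-fold, and regulatory T cell markers lay at 0.498-fold, a call that did not hold with an estimated correlation (adjusted p = 0.172). No single gene passed. These values were 0.666 without anti-B7-H3 2 for neutrophils and 0.640 without anti-B7-H3 1 for regulatory T cells. The count at an adjusted p of 0.05 was 0 by edgeR, with 425 genes at an unadjusted p under 0.05, 14 calls by DESeq2 and 2 by limma-voom. Without anti-B7-H3 3 the edgeR count was 1. Groups without overlap were found for 13.5% of tested genes, where chance gives 10%.

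Of 15 neutrophil markers, 0 passed over all genes and 4 were lower adjusted over the list alone, at a median of -0.98 (camera adjusted p = 9.24e-08, and adjusted p = 0.042 with an estimated correlation). S100a9 averaged 116 ± 29.3 CPM with anti-B7-H3 and 297 ± 59.6 with anti-PD1, and G0s2 averaged 35.5 ± 5.63 and 82.5 ± 24.9. Neutrophils were the single list of 22 called, 1 higher and 21 lower, that kept its call with an estimated correlation. Regulatory T cell markers had a median of -0.98 (-0.63 without anti-B7-H3 1) with no gene past either adjustment (camera adjusted p = 7.53e-10, and adjusted p = 0.172 with an estimated correlation), and the inhibitory receptor Ctla4 averaged 210 CPM with anti-B7-H3 and 511 with anti-PD1. Genes of TNF and NF-kB inflammation had a median of -0.55 (-0.35 without anti-B7-H3 1) and chemokine genes -0.46 (-0.29 without anti-PD1 2), each with 1 gene lower adjusted over the list alone (camera adjusted p = 4.23e-12 and 2.98e-06, and adjusted p = 0.0682 and 0.0697 with an estimated correlation). Cxcl2 averaged 63.1 ± 5.96 CPM with anti-B7-H3 and 186 ± 22.9 with anti-PD1. Heat-shock genes lay lower too, at a median of -0.37 (-0.23 without anti-PD1 2), with 2 of 16 genes lower adjusted over the list alone (camera adjusted p = 1.19e-05, and adjusted p = 0.219 with an estimated correlation). Immediate-early genes lay at -0.24 with no gene past either adjustment (camera adjusted p = 0.00576, and adjusted p = 0.143 with an estimated correlation), a call lost without anti-PD1 3 (camera adjusted p = 0.0548). Ribosomal protein genes, the list higher with anti-B7-H3, had a median of 0.48, or 0.73 without anti-B7-H3 3 (camera adjusted p = 0.00161, and adjusted p = 0.821 with an estimated correlation), but were not called without anti-PD1 1 (camera adjusted p = 0.151) and were lower, not higher, without anti-B7-H3 1, at a median of -0.17 (camera adjusted p = 0.00897). Macrophage markers, at a median of -0.18, were not called (camera adjusted p = 0.305). The named genes with the smallest p, none past the test at an edgeR adjusted p of 1.00, also included Mt1 at -1.13, Ifrd1 at -1.03, Mxd1 at -1.27, Dgat1 at -1.14, Polk at -1.02 and the immunoglobulin genes Ighv2-2 at 4.70, Iglc1 at -3.06 and Ighm at -1.21. Of these 10, Ighv2-2 alone was higher with anti-B7-H3.

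The 2 antibodies' effects against IgG were set side by side. Of the genes called higher with anti-B7-H3, 106 were also called higher with anti-PD1, among them C1qb, Mgl2, Arg1, Il1b and Atf3. No gene passed the test as lower with both. Groups simulated with no effect against the same controls shared 0.04 on average and 1 at most in 100 sets, which counts false calls rather than agreement, and independent lists of these sizes would share 1.88. The 3 genes called higher with anti-B7-H3 alone and the 121 with anti-PD1 alone all had positive fold changes with both antibodies, which shared controls also favour. Across all tested genes the signs matched for 75.2%, against 66.7% on average in the simulated sets. The direct comparison called no gene at all, and so 0 of these. Across the 13178 genes, which are not independent replicates, the fold changes correlated at r = 0.777, against 0.507 on average (0.469 to 0.556) in the simulated sets. Their covariance was 1.42 against 0.464, a difference of 0.952. The simulated sets used 1 dispersion per gene for all groups and independent genes, whereas IgG control 2 stood apart from the other controls. They may therefore understate the correlation that shared controls alone can give. The 3 controls are too few to be split into parts of at least 2 libraries, so part of the excess may come from the shared controls.

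**Figure D3:**
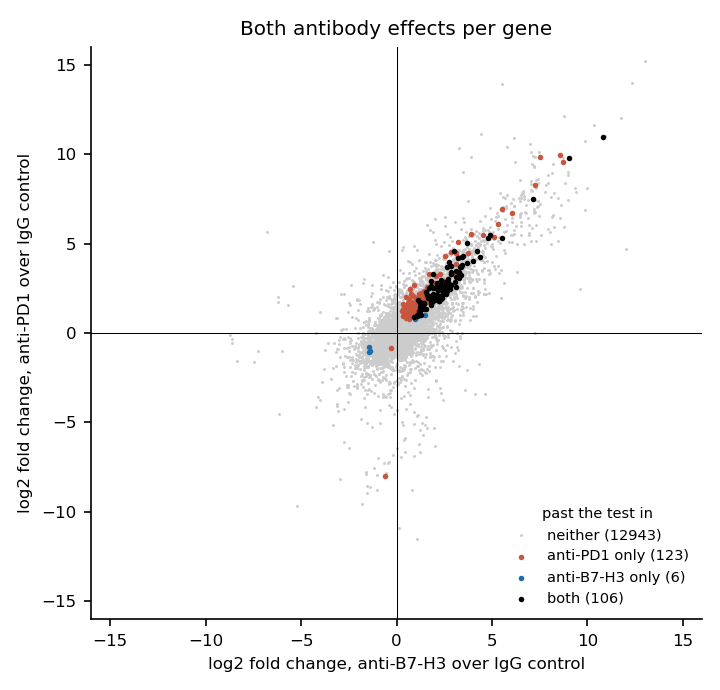
Log2 fold change over IgG with anti-B7-H3 (horizontal) and with anti-PD1 (vertical) for each of 13178 genes, coloured by the comparison in which it passed the test. The 106 genes higher with both antibodies lie along the diagonal, and the 2 axes share the same control libraries.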

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

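The comparison of macrophage markers with other cell types and the look at heat-shock genes were tests chosen only after their results had been seen. Anti-B7-H3 1 was singled out because 0.547% of its counts fell on transcripts that matched no gene and entered no comparison, above the highest control share of 0.316%.

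The same library was also high in some gene models that resemble repeats. These models, and Sirt5 below, were chosen after their values were seen. Gm21750 reached 2744 CPM there, against 42.8 to 249 in the other 8 libraries, Gm21897 2589 against 75.1 to 245, and Gm17555 1090 against 20.7 to 86.3. Not all such models were, since Gm10800, at 384 CPM, lay within the 12.9 to 617 of the others. Sirt5 reached 10990 CPM against 901 to 1934, and the repeat content of these genes was not examined. Olfactory and vomeronasal receptor genes, which immune cells are not known to transcribe widely, took 320 CPM in it and 553 of 1514 were detected, against 9.41 to 36.2 CPM and 29 to 222 detected elsewhere. The share was 8.83 times the highest of the other libraries, so traces of genomic DNA in this library are a candidate explanation. No biological explanation was tested, since the labels set this library apart from its group in no way.

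The macrophage list was higher with both antibodies. With all libraries thinned to 14441241 counts the smaller of the 2 medians was 3.39, with 94.4% of members positive in both comparisons. Fold changes are scaled to library size, so thinning could move them little and cannot decide on lower depth of the controls. Anti-B7-H3 1 had fewer counts (15091916) than IgG controls 1 and 3. Its list mean was 5.32 log2 CPM against their 2.43 and 2.30, which argues against depth for that library. Poorer capture in the controls is argued against too, where it depends on expression level alone. The list's median lay at percentile 100 of 10000 lists matched on mean expression, whose highest medians were 0.840 and 0.632. The match used the mean over all 9 libraries, antibody groups included. It therefore does not test a loss confined to transcripts scarce in the controls, where the list averaged 1.74 log2 CPM. A smaller share of T cell RNA would raise every other cell type alike, yet the macrophage list rose above the NK cell and plasmacytoid dendritic cell lists by 2.52 (log2) at the least, without overlap of the libraries. Both lists hold genes that are also in T cell lists, such as Prf1 and Lag3, which limits this test. The means of the B and plasma cell lists, not part of it, rose by 1.71 and 1.57 with anti-B7-H3, where the macrophage list rose by 3.48. With anti-PD1 these values were 0.853, 1.72 and 3.59. A larger share of macrophages after antibody treatment, or higher transcription in them, may account for the pattern and stays untested, because bulk RNA cannot part one from the other. Whether the sort was alike in all groups was not tested either. Among cells it should remove, list means with anti-B7-H3 and anti-PD1 were 6.24- and 7.65-fold for fibroblasts and 4.20- and 2.78-fold for melanoma. Erythroid markers went the other way, at 0.370- and 0.237-fold.

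Immediate-early genes were higher with both antibodies, in a list that also responds to tissue dissociation. Harsher handling of the treated tumours cannot be told apart from an effect of treatment: the heat-shock list, which handling could raise, had a median of 0.842 with anti-PD1 and 0.30 with anti-B7-H3, neither called with an estimated correlation. For anti-B7-H3 the median was 0.20 without IgG control 1 and the camera call was lost there (camera adjusted p = 0.538). It was also lost without anti-B7-H3 1, 2 or 3 or anti-PD1 3 (camera adjusted p = 0.0696, 0.0529, 0.0844 and 0.0814). More myeloid RNA, as a source of these transcripts, stays open as well. Across the 9 libraries centred on their groups, the list followed the macrophage list at rho = 0.283 (exact permutation p = 0.611) and r = 0.337 (exact permutation p = 0.593), or r = 0.159 without the 2 libraries farthest from the median, a relation these few libraries cannot settle. The labels give no batch, sorting day or handling time by which to split the libraries.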

How the results depend on the processing

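Of the tests here, the 3 settings that left out doubted libraries or genes at 0 were chosen only after the data had been seen. Under each setting most of the calls against IgG were higher, and their number depended on the tool and on the libraries. For anti-B7-H3 against IgG, the 112 calls became 393 with DESeq2 and 44 with only the 6 libraries compared, and leaving out 1 library gave 59 to 144. For anti-PD1 against IgG, the 229 became 660 with DESeq2 and 136 with only the 6 libraries compared, and leaving out 1 library gave 113 to 262. For anti-B7-H3 against anti-PD1, the count of 0 by edgeR, with 425 genes at an unadjusted p under 0.05, became 14 with DESeq2 and 2 with limma-voom, and leaving out 1 library gave 0 to 1. Fits with fewer libraries have fewer residual degrees of freedom, and for the other settings the cause was not tested. The other scalings, filters and gene sets stayed within 1.5 times each count. Without IgG control 2 and anti-PD1 3 the counts were 143, 234 and 0, without anti-B7-H3 1 as well they were 147, 270 and 0, and with only genes detected in all 9 libraries 135, 283 and 0. With no filter, the median of all genes moved to 0.162 for anti-B7-H3 against IgG and to 0.119 for anti-B7-H3 against anti-PD1, and fold changes under that setting are relative to those shifts.

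The gene lists called by camera numbered 33, 35 and 22 in the 3 comparisons, 10, 10 and 1 with an estimated correlation, and 18, 23 and 4 by fry. The other settings run on lists were 17, or 15 for lists left with too few genes under 2 of them. In all that could be run, 23 of the 33, 25 of the 35 and 12 of the 22 kept both call and direction. The correlation of the antibodies' effects was 0.778, 0.827 and 0.780 under the 3 alternatives run, against 0.777. Of the 106 calls of named genes, 45 held under every setting and 61 were lost under at least 1, and none changed sign while past the test.

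The replicate numbers were also used as a block, although nothing pairs the libraries: deviations from the group means of libraries with the same number correlated at -0.120 to 0.156, and 2 of the 9 libraries correlated best with their own number. The replicate block gave 64 and 127 genes against IgG and 0 in the direct comparison, and 33, 35 and 22 lists.

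The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For anti-B7-H3 against IgG the real split called 112 genes and was the 1 split with so many, the highest other giving 0. For anti-PD1 against IgG the real split called 229 and was the 1 split with so many, the highest other giving 0. For anti-B7-H3 against anti-PD1 the real split called 0, as many or more came from all 10 splits, and the highest other gave 1.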

Other observations

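No test here was chosen only after its result was seen, and the lists described are among those fixed in advance. A few further gene groups moved. Of 17 costimulation genes, 2 rose with anti-PD1 over all genes and 2 adjusted over the list alone, Tnfsf9, the ligand of 4-1BB, from 17.6 ± 2.47 to 72.3 ± 15.4 CPM (n = 3 per group) and Cd80 by 2.02 ± 0.43 (camera adjusted p = 0.0162, and adjusted p = 0.444 with an estimated correlation). The list's call was lost without IgG control 1, IgG control 3 or anti-PD1 3 (camera adjusted p = 0.117, 0.175 and 0.176). Of 20 glycolysis genes, 2 rose with anti-PD1 over all genes and 2 adjusted over the list alone, the lactate exporter Slc16a3 by 1.62 ± 0.20 and the glucose transporter Slc2a1 by 0.92 ± 0.19 (camera adjusted p = 0.00135, and adjusted p = 0.459 with an estimated correlation). Inhibitory ligands were higher with both antibodies, at means 2.15-fold with anti-B7-H3 and 2.17-fold with anti-PD1 (camera adjusted p = 0.00679 and 0.00209, and adjusted p = 0.105 and 0.077 with an estimated correlation). Of their 13 genes, Pdcd1lg2 passed over all genes with anti-PD1 and 3 adjusted over the list alone, and none passed either adjustment with anti-B7-H3. In each comparison 9 of the 13 had positive fold changes. The median with anti-B7-H3 was 0.80, or 0.51 without IgG control 2. With anti-PD1 it was 0.98, and ran from 0.30 without anti-PD1 1 to 1.47 without IgG control 1. Hdc, which makes histamine, went with anti-PD1 from 4.98 ± 3.82 to 98.5 ± 10.4 CPM, while the list of mast cells and basophils it belongs to had a median of -0.41 and was not called (camera adjusted p = 0.751). The neutrophil list holds Hdc as well.

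Variable segments of the immunoglobulin heavy chain took 748 ± 446 CPM in the controls, 1468 ± 334 with anti-B7-H3 and 3172 ± 731 with anti-PD1, and those of the kappa chain 1799 ± 1234, 3078 ± 649 and 6083 ± 619. Those of the T cell receptor alpha chain took 778, 540 and 606 CPM and those of the beta chain 715, 575 and 465. The smallest exact permutation p among the 24 comparisons of segments was 0.1, the smallest that 3 against 3 can give, and 0.267 after Benjamini-Hochberg adjustment.

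A narrower choice of segments after treatment, as clonal expansion could give, was tested as a hypothesis through the effective number of segments. For the beta chain the controls averaged 16.5, anti-B7-H3 17.2 and anti-PD1 16.8. For the heavy chain they averaged 12.1, 17.6 and 19.1, for the kappa chain 10.5, 16.4 and 16.5 and for the alpha chain 62.1, 65.5 and 60.0. In none were all libraries of an antibody group lower than all controls, so no narrowing was seen. For the kappa chain all 3 anti-B7-H3 libraries were higher than all controls (exact permutation p = 0.1). Anti-B7-H3 1, where genomic DNA was a candidate above, had 75 of 100 kappa segments at 10 counts or more, against 21 to 57 in the other libraries. Whether such reads raised its effective number of 15.3 was not tested. In the other comparisons the antibody groups overlapped with the controls, and 3 libraries each, with reads that similar segments can share, exclude no narrowing of clones within a segment.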
